A study of Mus musculus with 24 samples.

How the data were processed

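The deposited file of each library gives several read counts per gene. The main count was the number of all reads in the exons of a gene, as the authors deposited it. The count of reads placed uniquely in exons and the count of all reads of a gene with its introns were used only as alternatives. Read alignment was done by the authors, whose processing notes name the mouse build mm10, and was not repeated here. Per the labels, total RNA came from excised whole bladders, was depleted of ribosomal RNA and was made into directional libraries. The deposited table for week 16 was used for 3 columns. Its p-value is, per the file headers, that of the authors' test with tagwise dispersions between 3 WT and 3 knockout libraries, and a p-value corrected by false discovery rate stands beside it. Its fold change is, per the file headers, a signed ratio of knockout over WT, negative where WT was higher. The 126 columns of values per sample in that table were not used here. A deposited table of log2 values for 2028 genes had been scaled by the authors, and its choice of genes and order of steps are not given in the sources used here.

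Counts of 24 libraries were read for 49585 genes, and genes with too few reads were removed with filterByExpr of edgeR at a minimum count of 10, which left 16189 genes. Libraries were scaled by the TMM method. The model held 8 coefficients, 1 for each genotype at each time, and an additive term for the file series, since replicate 1 of every group carried 1 series number and replicates 2 and 3 the other. Genes were tested with edgeR's quasi-likelihood test (version 4.0.16, robust fit, R 4.3.3) with Benjamini-Hochberg adjustment over all tested genes of a comparison. A gene was counted as changed at an adjusted p of at most 0.05. The fit left 15 residual degrees of freedom, its common biological coefficient of variation was 0.247, and the median prior degrees of freedom were 2.92. A log2 change is given with its standard error (SE) from this fit, CPM values are counts scaled to library size by edgeR's cpm, and group values are means ± standard deviation (SD) of 3 libraries.

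The comparisons were each BBN time against untreated bladder within WT and within the knockout, knockout against WT at each of the 4 times, the average of these 4 differences, the difference between the genotypes in the week 16 response, and a test for any such difference over the 3 treated times. The comparisons, the model, 31 gene lists, the rule for naming genes and a first set of alternatives were chosen before the data were examined. Named genes were Pld1 and Mmp13 in every comparison, the 8 largest rises and 8 largest falls per comparison, and up to 4 members per list, those with the smallest p. Some further list members, such as Krt5, Krt19, Nos2, Fos and Egr1, were named after their values were seen. The rises and falls needed an adjusted p of at most 0.05, a mean of at least 1 CPM and no overlap between the CPM values of the compared groups. Where a gene had no read in 1 group, the fold change is given as a lower bound with 3 reads set in that group. Where it had 1 to 3 reads, the ratio of library-scaled reads is given with its exact 95% counting interval. Such bounds and intervals cover counting error only, not the spread between bladders. The list medians were also computed with genes at 0 set to their bound.

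Of the 31 lists, 28 with at least 3 tested members were tested with camera of limma (version 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Each list result was also computed with the correlation estimated from the residuals. Lists covered the phospholipase D family, matrix metalloproteinases, metalloproteinase inhibitors, NF-kB target genes, umbrella and luminal urothelium, basal urothelium, squamous differentiation, cell proliferation, p53 response and DNA damage, and epithelial-mesenchymal transition. They further covered collagens and extracellular matrix, activated fibroblasts, bladder smooth muscle, skeletal muscle, endothelium, T and NK cells, B and plasma cells, macrophages and dendritic cells, neutrophils and acute inflammation, mast cells, and MHC class II antigen presentation. The remaining lists were interferon response, adipose tissue, male accessory glands, nerve and glia, erythrocytes, immediate-early and dissociation stress, sex-linked genes, xenobiotic metabolism, glycolysis and hypoxia, and oxidative phosphorylation. The phospholipase D, male accessory gland and sex-linked lists were read by gene only. Ccn2, Igj, Itgam, Semg1, Hbb-b1 and Hbb-b2 were list members absent from the files under these symbols.

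The alternatives fixed in advance were unique exon reads, reads with introns, no file series term, no gene filter, RLE scaling, a fit of only the compared libraries, a block for the replicate number, DESeq2 (version 1.42.0), each library left out in turn, and the estimated correlation for lists. DESeq2 was run with its Wald test, and with its likelihood ratio test for a differing response at any time. Chosen after seeing the data were fits without the 2 libraries lowest in smooth muscle genes (replicate 1 of WT and of the knockout at 12 weeks), lists with each library left out, and an exact test of edgeR on the 6 libraries of week 16. The libraries of each 3 against 3 comparison were also split in all other ways, and genes were counted as in the real split. For the average over 4 times and the differing response, genotype labels were drawn at random within each time, giving 100 splits with the real one. A set of 3 against 3 libraries without any difference separates completely for 10% of genes. Genes within 1 Mb of each other and genes within 10 Mb of Pld1 were counted, the first against 10000 random gene sets.

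The fit was tested on simulated data with the same design, in which 200 genes per set were changed. Of genes changed by a log2 of 1, 49% were found for knockout against WT at week 16, 86.7% for the average over 4 times and 14% for the difference in response. At a log2 of 2 the shares were 81.2%, 95.9% and 62.6%, and 2.47% to 5.53% of called genes were false. Each simulated gene was drawn on its own around the mean of its week. Shifts shared by many genes, such as those of tissue content, were therefore not simulated. In the real counts a wrong split of the 12 week libraries gave 2882 calls, so these shares need not hold for the real libraries.

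The labels do not state that each library came from a separate animal, and the series design names bladders of sacrificed mice in triplet samples. Each p-value therefore sets a difference against the spread between these samples, which the main fit pooled over all 24 libraries. Read-level data, histology and tumour stage were not used here. Results for some single genes are not reported here.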

Results

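Gene expression was measured by RNA sequencing of whole bladders from wild-type (WT) C57BL/6 mice and mice lacking phospholipase D1 (PLD1 knockout). Bladders were untreated or had received the bladder carcinogen N-butyl-N-(4-hydroxybutyl)nitrosamine (BBN) for 8, 12 or 16 weeks. The labels call the untreated groups pre, and no group was kept untreated for 8, 12 or 16 weeks. BBN therefore cannot be told apart from age or date of collection. Genes named below as changed by or with BBN are those that differed from the untreated groups. Each of the 8 groups had 3 libraries, 24 in all. A library held 5436830 (WT at 16 weeks, replicate 2) to 11842051 (WT at 16 weeks, replicate 3) reads in exons, with a median of 9290251.5. Of 49585 genes in the files, 16189 had enough reads to be tested. Xist, the transcript of the silenced X chromosome, stood at 1297 ± 813.9 to 2790 ± 537.9 CPM (SD, n = 3) in the 8 groups, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty did not pass the read filter.

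Tissue markers differed between libraries of 1 group. Smooth muscle genes, among them Myh11, Actg2 and Des, had a mean log2 CPM of 5.019 in replicate 1 of WT at 12 weeks and 4.566 in replicate 1 of the knockout at 12 weeks, against 6.781 or more in the other 22 libraries. Adipose genes such as Adipoq and Plin1 reached 8.667 and 7.671 in replicates 1 and 2 of the knockout at 12 weeks, against 2.343 in replicate 1 of WT at 12 weeks. Skeletal muscle genes such as Acta1 and Ckm stood at 5.264 in replicate 3 of the knockout at 8 weeks and at 3.012 or less elsewhere. Replicates of 1 group had a correlation of log2 CPM of 0.964 to 0.984 across genes, except at 12 weeks, where the lowest value was 0.890 in WT and 0.917 in the knockout. Reads in introns made up 31.32% to 48.95% of the reads of a library. Untreated libraries held 40.01% to 47.55%, those of 8 weeks 31.39% to 35.34%, of 12 weeks 31.32% to 38.39% and of 16 weeks 36.34% to 48.95%. The share at 8 and 12 weeks thus lay below every untreated library, and whether it bears on the changes with BBN was not tested.

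Pld1 (ENSMUSG00000027695, chromosome 3, 27938695 to 28133362, mm10), the gene targeted in the knockout, was lower in every knockout library than in every WT library. WT libraries held 27.78 to 65.31 CPM and knockout libraries 8.763 to 23.1 CPM. Group means in WT were 59.3 ± 5.26 CPM untreated and 53.3 ± 1.77, 39.2 ± 4.30 and 36.4 ± 7.64 CPM at 8, 12 and 16 weeks (SD, n = 3). In the knockout they were 19.4 ± 3.48, 11.6 ± 2.54, 9.20 ± 0.447 and 12.8 ± 0.878 CPM. The log2 difference averaged over the 4 times was −1.85 ± 0.09 (SE, edgeR quasi-likelihood test, adjusted p = 1.67e-10), so 0.363 or less of the WT exon reads remained at each time. Reads in Pld1 introns did not fall with them, with a knockout to WT ratio of 0.939, 0.849, 0.902 and 1.34 at the 4 times. With reads counted over introns too, the Pld1 difference therefore did not pass at any time (log2 −0.44, −0.69, −0.77 and −0.11, adjusted p from 0.625 to 1). Within WT, Pld1 fell with BBN by 12 weeks (log2 −0.60 ± 0.16, adjusted p = 0.0105) and 16 weeks (−0.70 ± 0.16, 0.00412), and the 12 week call was lost without replicate 1 of untreated WT, without replicate 1 of WT at 12 weeks, and in a fit of the compared libraries only. In the knockout the remaining Pld1 reads also fell, by −0.74 ± 0.17, −1.08 ± 0.18 and −0.60 ± 0.17. The 12 week call was lost with only the compared libraries fitted, and that of 16 weeks with introns counted and without replicates 2 or 3 of the untreated knockout or of the knockout at 16 weeks.

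**Figure D1:**
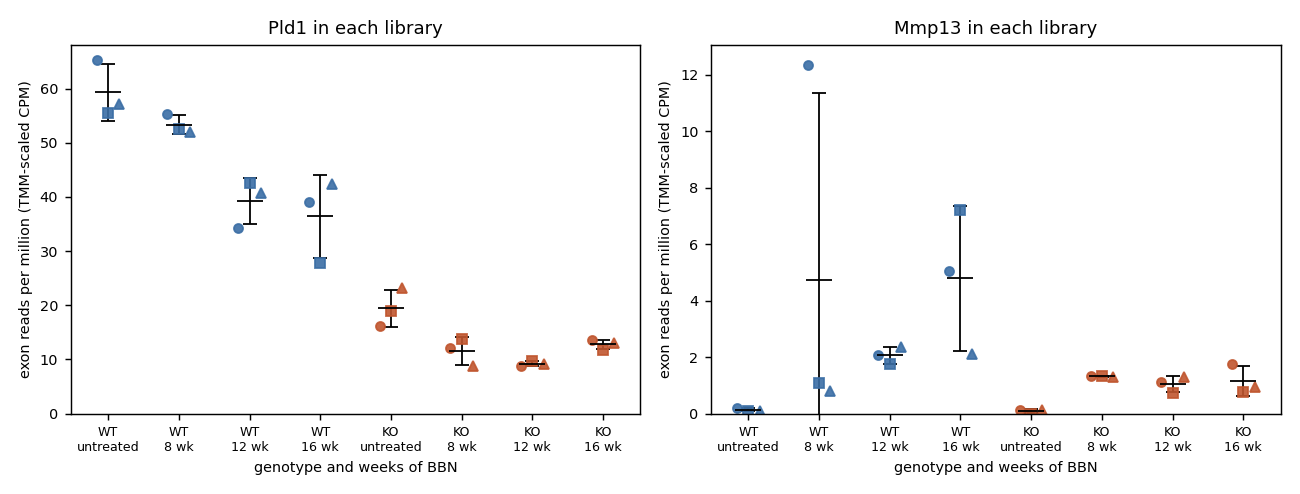
Library-scaled counts (CPM) of Pld1 and Mmp13 in each of the 24 libraries by week of BBN, with WT in blue, the knockout in orange, symbols for replicates 1 to 3 and bars for the mean ± SD. Every knockout library (8.763 to 23.1 CPM) lay below every WT library (27.78 to 65.31 CPM) for Pld1, and Mmp13 reached 12.35 CPM in a single WT library at 8 weeks.

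The first comparison asked what differed between WT bladders after 8 weeks of BBN and untreated ones. Epithelial keratins of injured and stratified epithelium appeared, uroplakins fell, and genes of dividing cells, interferon response and most immune cell types rose. Krt6a (ENSMUSG00000058354, chromosome 15, 101689932 to 101694307), a keratin of activated epithelium, rose from 0 reads to 132.6 ± 67.41 CPM (SD, n = 3), at least 1330-fold. Sprr2g (ENSMUSG00000046203, chromosome 3, 92373915 to 92375229) rose at least 318-fold, the iron binding protein gene Ltf at least 274-fold, the tight junction gene Cldn3 at least 170-fold and the neutrophil attractant Cxcl5 at least 121-fold. Of 16189 genes, 3489 changed (2102 higher and 1387 lower). Without replicate 1 of WT at 8 weeks 2231 changed, and with only the compared libraries fitted 5768 did, 3221 of them shared. The Ltf call was lost when only the compared libraries were fitted.

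Within the urothelium at 8 weeks, the basal keratin Krt14 rose by a log2 of 8.18 ± 0.53 (SE, adjusted p = 8.32e-08) and the desmosome gene Dsg3 by 8.00 ± 0.66 (8.3e-07). Of 14 basal genes 7 rose and 3 fell (9 and 4 adjusted over the list alone), with a median log2 change of 0.83 (camera adjusted p = 0.00456, and adjusted p = 0.484 with an estimated correlation). Of 24 squamous differentiation genes 15 rose (15 adjusted over the list alone), including Sprr2f (10.08 ± 0.83, adjusted p = 8.3e-07) and Pkp1 (2.69 ± 0.33). The squamous median was 1.99, or 1.81 with genes at 0 set to their bound (camera adjusted p = 3.53e-08, and adjusted p = 0.167 with an estimated correlation). Of 25 umbrella and luminal genes 8 fell and 3 rose (9 and 3 adjusted over the list alone), with a median of −0.67 (camera adjusted p = 0.00887, and adjusted p = 0.599 with an estimated correlation). The uroplakin Upk1a fell by −3.07 ± 0.53, Upk2 by −2.21 ± 0.40 and Upk3b by −1.62 ± 0.35, while Krt19 rose by 1.29 ± 0.31.

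Of 28 proliferation genes 25 rose at 8 weeks (27 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 4.01e-15, and adjusted p = 0.167 with an estimated correlation), and Birc5 rose by 2.39 ± 0.34 and the mitotic kinase gene Plk1 by 2.10 ± 0.30. The p53 list rose with 16 of 20 genes (17 adjusted over the list alone), a median of 0.90 and Cdkn1a at 2.34 ± 0.20 and Pmaip1 at 2.94 ± 0.32 (camera adjusted p = 1.44e-09, and adjusted p = 0.0589 with an estimated correlation). Interferon response genes rose in 19 of 21 cases (20 adjusted over the list alone), with a median of 2.67 (camera adjusted p = 8.76e-19, and adjusted p = 0.0994 with an estimated correlation). Isg15 rose by 4.57 ± 0.55 and Oas2 by 2.67 ± 0.29. Of 28 NF-kB target genes 17 rose and 1 fell (20 and 2 adjusted over the list alone), with a median of 1.35 (camera adjusted p = 3.38e-10, and adjusted p = 0.0589 with an estimated correlation). Icam1 rose by 1.67 ± 0.14 and Bcl3 by 2.32 ± 0.23, whereas Nos2 fell by −1.58 ± 0.40.

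Leukocyte genes rose at 8 weeks of BBN in WT. All 9 neutrophil genes rose (9 adjusted over the list alone), with S100a9 at least 18.6-fold higher and a list median of 6.22, or 3.69 with genes at 0 set to their bound (camera adjusted p = 3.3e-06, and adjusted p = 0.0994 with an estimated correlation). B and plasma cell genes rose in 16 of 21 cases (16 adjusted over the list alone), with a median of 3.69, Jchain at 7.40 ± 1.01 and Pou2af1 at 5.37 ± 0.56 (camera adjusted p = 1.9e-08, and adjusted p = 0.167 with an estimated correlation). T and NK cell genes rose in 13 of 21 cases (15 adjusted over the list alone), with a median of 2.53 and Foxp3 at 4.85 ± 0.72 (camera adjusted p = 8.45e-08, and adjusted p = 0.343 with an estimated correlation). Macrophage and dendritic cell genes rose in 13 of 18 cases (16 adjusted over the list alone), with Itgax at 2.65 ± 0.27 and Ccr7 at 4.53 ± 0.48 (camera adjusted p = 3.53e-08, and adjusted p = 0.246 with an estimated correlation). MHC class II genes rose in 9 of 10 cases (9 adjusted over the list alone), with H2-Ab1 at 2.28 ± 0.51 and Ciita at 2.31 ± 0.52 (camera adjusted p = 1.89e-05, and adjusted p = 0.358 with an estimated correlation).

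Matrix-degrading enzymes also rose at 8 weeks in WT. Mmp13 had 127 reads in the 3 treated libraries against 4 untreated, a ratio of library-scaled reads of 34.1 (95% interval 13 to 127) and a log2 change of 4.66 ± 0.88 (adjusted p = 0.00115). Replicate 1 held 108 of these 127 reads, and without it the log2 change was 2.84 and still passed. Of 17 matrix metalloproteinases 8 rose (8 adjusted over the list alone), including Mmp25 (4.16 ± 0.63) and Mmp12 (2.87 ± 0.56), with Mmp7 at least 78.7-fold higher (camera adjusted p = 0.000959, and adjusted p = 0.246 with an estimated correlation). Their inhibitor Timp1 rose by 3.02 ± 0.63. Among fibroblast genes Il33 rose by 4.18 ± 0.38 and Grem1 by 8.24 ± 1.21. Smooth muscle genes had a median of −0.70 and none of 18 passed.

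The largest falls at 8 weeks in WT were in genes of low or moderate level. The transport protein gene Ttr (ENSMUSG00000061808, chromosome 18, 20665250 to 20674324) had 1 read against 352 (interval of the ratio 58.5 to 13000), and Dmgdh was at least 25.2-fold lower. Cyp4f15 fell from 108.0 ± 20.12 to 2.956 ± 1.161 CPM (log2 −5.18 ± 0.79) and 4932411E22Rik from 116.3 ± 32.6 to 2.408 ± 1.231 CPM (−5.59 ± 0.88). Dmbt1, Igf2bp1, Shisa7 and RP23-386F15.2 were the other 4 of the 8 largest falls. The neuronal gene Uchl1 fell by −4.53 ± 0.46 while Snap25 rose by 3.67 ± 0.77.

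At 12 weeks of BBN in WT, the second time of the course, 5226 genes changed (2981 higher and 2245 lower), and 1514 did with only the compared libraries fitted, 1504 of them shared. Krt6a was at least 3320-fold higher at 316.0 ± 178.2 CPM (SD, n = 3), Ltf at least 1290-fold and Cldn3 at least 384-fold. Krt13, a keratin of stratified epithelium, rose by 10.74 ± 1.18 (SE, adjusted p = 7.57e-06), and Krt16 was at least 219-fold higher, a call lost with only the compared libraries fitted. Squamous genes rose in 20 of 24 cases (21 with 1 fall adjusted over the list alone), with a median of 3.59, or 3.11 with genes at 0 set to their bound (camera adjusted p = 2.85e-13, and adjusted p = 0.182 with an estimated correlation). Krt14 rose by 9.85 ± 0.56 and Krt5 by 1.91 ± 0.33, and of 14 basal genes 9 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00011, and adjusted p = 0.44 with an estimated correlation). Luminal genes went both ways, with 5 higher and 6 lower (6 and 6 adjusted over the list alone), Elf3 at 2.25 ± 0.37 and Upk1a at −1.77 ± 0.51. Their median was 0.10 while the camera direction was down, and the list did not pass (adjusted p = 0.885).

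Of 28 proliferation genes 27 rose at 12 weeks (27 adjusted over the list alone), with a median of 1.98 and Birc5 at 3.23 ± 0.34 (camera adjusted p = 2.78e-17, and adjusted p = 0.182 with an estimated correlation). The interferon list rose with 17 genes (20 adjusted over the list alone) and a median of 3.02 (camera adjusted p = 2.09e-15, and adjusted p = 0.182 with an estimated correlation). NF-kB targets rose with 18 genes and 1 fall (19 and 1 adjusted over the list alone), Icam1 at 1.36 ± 0.14 (camera adjusted p = 6.03e-06, and adjusted p = 0.182 with an estimated correlation). T and NK genes rose in 7 of 21 cases (10 adjusted over the list alone), with Foxp3 at 3.87 ± 0.72 (camera adjusted p = 0.00251, and adjusted p = 0.71 with an estimated correlation), and the list call was lost without replicate 3 of WT at 12 weeks (0.0517). Collagen genes fell in 6 of 26 cases and rose in 1 (0 and 1 adjusted over the list alone), with a median of −1.34 (camera adjusted p = 0.000339, and adjusted p = 0.71 with an estimated correlation). Col1a1 fell by −2.37 ± 0.78 and Col6a3 by −2.22 ± 0.72, while Spp1 rose by 3.72 ± 0.82. The Col1a1 and Col6a3 calls were lost without replicate 2 or 3 of untreated WT or replicate 3 at 12 weeks and with only the compared libraries fitted. Smooth muscle genes had a median of −1.24 with none of 18 passing alone (camera adjusted p = 0.000941, and adjusted p = 0.71 with an estimated correlation), and replicate 1 at 12 weeks was the library low in these genes and in collagen genes. Without it the median was −0.74 for collagen genes (adjusted p = 0.0207) and −0.65 for smooth muscle genes (0.0223). Mmp13 rose by 3.92 ± 0.90 (adjusted p = 0.0034), with 58 reads against 4 and a ratio of 16.2 (95% interval 6.01 to 61.6). Among the largest falls, Unc13c went from 22.99 ± 2.457 to 0.6413 ± 0.3282 CPM (−5.13 ± 0.52) and Plppr5 from 256 reads to 3 (interval of the ratio 25.8 to 372).

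At 16 weeks of BBN in WT, the last time, 5284 genes changed (2913 higher and 2371 lower). Without replicate 1 of untreated WT 3228 changed, and without replicate 2 of WT at 16 weeks 3222 did. Krt6a reached 371.0 ± 134.5 CPM (SD, n = 3, at least 3680-fold), Tff1 rose at least 391-fold, Sprr2g at least 526-fold, Krt16 at least 252-fold and Sprr2f by 11.21 ± 0.84 (SE, adjusted p = 2.03e-07). Squamous genes rose in 21 of 24 cases (22 adjusted over the list alone), with a median of 2.93, unchanged with genes at 0 set to their bound (camera adjusted p = 7.41e-14, and adjusted p = 0.132 with an estimated correlation). Krt14 rose by 10.24 ± 0.56, Krt5 by 2.42 ± 0.34 and Cd44 by 2.19 ± 0.22, and 9 of 14 basal genes rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 6.33e-06, and adjusted p = 0.393 with an estimated correlation). Luminal genes rose in 7 and fell in 5 of 25 cases (8 and 5 adjusted over the list alone, camera adjusted p = 0.392), with Elf3 at 2.37 ± 0.37 and Upk1a at −2.09 ± 0.51. All 28 proliferation genes rose, with a median of 2.17, Plk1 at 3.04 ± 0.31 and the replication gene Mcm2 at 1.49 ± 0.15 (camera adjusted p = 2.82e-19, and adjusted p = 0.17 with an estimated correlation).

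Immune and matrix genes at 16 weeks in WT kept the directions of 12 weeks. Interferon genes rose in 17 of 21 cases (18 adjusted over the list alone), with a median of 2.53 (camera adjusted p = 7.41e-14, and adjusted p = 0.17 with an estimated correlation). Of the NF-kB targets 19 rose and 1 fell (21 and 1 adjusted over the list alone), with Bcl3 at 2.50 ± 0.23 (camera adjusted p = 1.28e-07, and adjusted p = 0.132 with an estimated correlation). All 9 neutrophil genes rose, with a median of 4.52, or 3.33 with genes at 0 set to their bound (camera adjusted p = 0.000121, and adjusted p = 0.17 with an estimated correlation). Of 26 collagen and matrix genes 10 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of −1.53 and Col1a1 at −2.71 ± 0.79 (camera adjusted p = 0.00174, and adjusted p = 0.688 with an estimated correlation). Of 18 smooth muscle genes 5 fell (16 adjusted over the list alone), with a median of −1.66 and Casq2 at −2.21 ± 0.70 (camera adjusted p = 0.00053, and adjusted p = 0.688 with an estimated correlation). Mmp13 rose by 5.08 ± 0.87 (adjusted p = 0.000367), with 110 reads against 4 and a ratio of 33.1 (95% interval 12.6 to 124). Mmp12 rose by 3.87 ± 0.55 and Mmp15 by 1.85 ± 0.26, while the inhibitor Reck fell by −1.70 ± 0.41. Among the largest falls were the neuronal adhesion genes Cdh18, at least 31.6-fold lower, and Nrxn3, at least 26-fold lower, and AI593442 (−6.20 ± 0.80).

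The same 3 comparisons within the knockout asked what differed after BBN without PLD1. At 8 weeks 3503 genes changed (1629 higher and 1874 lower). The number was 2055 without replicate 2 and 2108 without replicate 3 of the untreated knockout, 2312 without replicate 3 of the knockout at 8 weeks, 5331 with introns counted, and 5316 without the 2 libraries low in smooth muscle. More genes rose than fell in that last fit (3026 and 2290) and without replicate 2 (1093 and 962) or 3 (1142 and 966) of the untreated knockout. The same held without replicate 2 (1352 and 1071) or 3 (1283 and 1029) at 8 weeks, and with only the compared libraries fitted (1992 and 1984). Krt6a rose from 0 reads to 126.7 ± 27.38 CPM (SD, n = 3, at least 1040-fold), Cxcl5 at least 79.3-fold, Mmp7 at least 78.5-fold and Tff1 at least 50.2-fold. The immunoglobulin segments Igkv4-55 and Igkv16-104 were at least 104-fold and 60.1-fold higher, but mostly in single libraries (12.61 ± 20.59 and 7.319 ± 11.32 CPM), and both calls were lost in 6 alternatives. Krt14 rose by 6.80 ± 0.49 (SE, adjusted p = 1.07e-06), and 10 of 24 squamous genes rose (14 adjusted over the list alone), with a median of 1.18 (camera adjusted p = 6.31e-06, and adjusted p = 0.31 with an estimated correlation). Luminal genes fell in 10 of 25 cases and rose in 2 (11 and 4 adjusted over the list alone), with Upk2 at −2.10 ± 0.40 and Gata3 at −1.66 ± 0.35 (camera adjusted p = 0.00836, and adjusted p = 0.62 with an estimated correlation).

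Of 28 proliferation genes 13 rose at 8 weeks in the knockout (18 adjusted over the list alone), with a median of 0.87, Plk1 at 1.03 ± 0.29 and Rrm2 at 1.32 ± 0.32 (camera adjusted p = 8.44e-06, and adjusted p = 0.487 with an estimated correlation). Interferon genes rose in 19 of 21 cases (19 adjusted over the list alone), with a median of 2.72 (camera adjusted p = 4.97e-20, and adjusted p = 0.0911 with an estimated correlation). NF-kB targets rose in 16 of 28 cases (20 adjusted over the list alone), with Icam1 at 1.38 ± 0.14 (camera adjusted p = 3.35e-11, and adjusted p = 0.0624 with an estimated correlation). Immediate-early genes rose in 19 of 23 cases (21 adjusted over the list alone), with Fos at 2.87 ± 0.56, Egr1 at 3.52 ± 0.65 and Junb at 1.56 ± 0.18 (camera adjusted p = 3.4e-14, and adjusted p = 0.0911 with an estimated correlation). In WT at that time the list rose too, with a median of 0.57 and 4 of the 23 genes (camera adjusted p = 0.00456, and adjusted p = 0.484 with an estimated correlation), a call lost without replicate 1 of untreated WT (0.212), and Fos stood at −0.25 ± 0.52. Untreated, the list stood lower in the knockout than in WT, with a median of −0.25 (camera adjusted p = 1.64e-05, and adjusted p = 0.715 with an estimated correlation), a call lost without replicate 3 of untreated WT (0.175). Mmp13 rose by 3.90 ± 1.05 (adjusted p = 0.013), with 39 reads against 2 and a ratio of 16.1 (95% interval 4.16 to 137). Of 17 metalloproteinases 7 rose (7 adjusted over the list alone, camera adjusted p = 0.00202, and adjusted p = 0.31 with an estimated correlation). The largest falls included Igf2bp1 and Dmgdh, both at least 31.6-fold lower, Dab1 (−5.49 ± 0.74) and Ttr with 3 reads against 268 (interval of the ratio 36.7 to 529).

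At 12 weeks in the knockout 5302 genes changed (2829 higher and 2473 lower), with 365 in a fit of the compared libraries only and 3504 without replicate 3 of the knockout at 12 weeks. Without replicate 1 of the untreated knockout 2090 were higher and 2151 lower. Krt6a was at least 1750-fold higher (198.8 ± 86.92 CPM, SD, n = 3) and Tff1 at least 224-fold, and the calls of Tff1 and of Dmgdh (2 reads against 78, interval of the ratio 10.5 to 330) were lost in a fit of the compared libraries only. The mast cell protease genes Mcpt1 and Mcpt2 were at least 98.2-fold and 67.5-fold higher, with 12.69 ± 20.71 and 8.732 ± 14.28 CPM, and lost their calls without replicate 3. Squamous genes rose in 16 of 24 cases (17 with 2 falls adjusted over the list alone), with a median of 2.63, or 1.97 with genes at 0 set to their bound (camera adjusted p = 4.24e-09, and adjusted p = 0.159 with an estimated correlation). Krt14 rose by 8.24 ± 0.52 (SE), Krt17 by 6.74 ± 0.99 and Sncg by 3.49 ± 0.57. Proliferation genes rose in 23 of 28 cases (24 adjusted over the list alone), with a median of 1.36 (camera adjusted p = 4.24e-09, and adjusted p = 0.322 with an estimated correlation). Genes of oxidative phosphorylation rose in 17 of 25 cases (20 adjusted over the list alone), with Uqcrc1 at 0.71 ± 0.10 and Sdhb at 0.75 ± 0.12 (camera adjusted p = 2.56e-07, and adjusted p = 0.322 with an estimated correlation). Ldha rose by 1.19 ± 0.14. Replicate 2 of this group stood apart, with 1.131% mitochondrial reads against 3.35% and 3.396% and with 2.217% of reads from Gm26917 and 0.9337% from ribosomal RNA, the highest of all 24 libraries. Without it 5686 genes changed and the oxidative phosphorylation list had a median of 0.53.

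Adipose genes rose at 12 weeks in the knockout in 7 of 11 cases (9 adjusted over the list alone), with a median of 2.97 and Retn at 3.87 ± 1.11 (camera adjusted p = 0.016, and adjusted p = 0.575 with an estimated correlation). This list call was lost without replicate 1 of the knockout at 12 weeks, the library with the highest adipose level, and without replicate 3 of the untreated knockout (up to 0.196). Smooth muscle genes fell in 6 of 18 cases (6 adjusted over the list alone), with a median of −1.72 and Chrm2 at −2.90 ± 0.85 (camera adjusted p = 0.000531, and adjusted p = 0.575 with an estimated correlation), a list call lost without the same replicate 1 (0.0574, median −1.09). The Chrm2 call was lost without it too, without replicate 1 of the untreated knockout (−1.63) and with only the compared libraries fitted. Collagen and matrix genes fell in 11 of 26 cases and rose in 1 (14 and 1 adjusted over the list alone), with Col1a1 at −2.50 ± 0.79 (camera adjusted p = 0.000895, and adjusted p = 0.575 with an estimated correlation). The Col1a1 call was lost without replicate 1 of the untreated knockout or replicate 1 or 3 at 12 weeks and with only the compared libraries fitted. Mmp13 rose by 3.53 ± 1.09 (adjusted p = 0.0202), with 27 reads against 2 and a ratio of 13.4 (95% interval 3.37 to 116), and passed in 11 of 14 alternatives (adjusted p from 0.0118 to 0.0792). The call was lost without replicate 1 or 2 of the untreated knockout or replicate 3 at 12 weeks. The receptor gene Kl fell by −5.26 ± 0.61 (adjusted p = 1.48e-05).

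At 16 weeks in the knockout 2779 genes changed (1436 higher and 1343 lower). The number was 1646 without replicate 2 and 1720 without replicate 3 of the untreated knockout, 1708 without replicate 1 of the knockout at 16 weeks and 4414 without the 2 libraries low in smooth muscle. Without replicate 1 of the untreated knockout 1259 were higher and 1620 lower. Krt6a reached 271.2 ± 76.33 CPM (SD, n = 3, at least 2290-fold), and the cornified layer genes Krt16, Sprr3 and Crnn rose at least 164-fold, 138-fold and 133-fold. Squamous genes rose in 17 of 24 cases (18 adjusted over the list alone), with a median of 3.04, or 3.02 with genes at 0 set to their bound (camera adjusted p = 6.02e-15, and adjusted p = 0.0617 with an estimated correlation). Luminal genes fell in 8 of 25 cases and rose in 3 (9 and 4 adjusted over the list alone), with Upk3a at −2.58 ± 0.48 (SE) and Krt20 at −3.47 ± 0.83 (camera adjusted p = 0.039, and adjusted p = 0.752 with an estimated correlation). This list call was lost without replicates 2 or 3 of the untreated knockout or replicate 1 of the knockout at 16 weeks (up to 0.136). Proliferation genes rose in 21 of 28 cases (23 adjusted over the list alone), with a median of 1.18, Rrm2 at 1.76 ± 0.33 and Plk1 at 1.51 ± 0.29 (camera adjusted p = 3.51e-10, and adjusted p = 0.268 with an estimated correlation). Interferon genes rose in 19 of 21 cases (21 adjusted over the list alone), with a median of 3.02 (camera adjusted p = 1.85e-25, and adjusted p = 0.0617 with an estimated correlation). NF-kB targets rose in 14 of 28 cases (19 adjusted over the list alone), with Bcl3 at 1.95 ± 0.22 (camera adjusted p = 8.25e-11, and adjusted p = 0.0617 with an estimated correlation). Mmp13 rose by 3.59 ± 1.06 (adjusted p = 0.0265), with 35 reads against 2 and a ratio of 14.6 (95% interval 3.74 to 125), and passed in 9 of 14 alternatives (adjusted p from 0.0164 to 0.0912). The call was lost without any 1 of the 3 untreated knockout libraries and without replicate 1 or 3 at 16 weeks. Collagen and smooth muscle lists had medians of −0.71 (camera adjusted p = 0.249) and −0.64 (0.324).

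**Figure D2:**
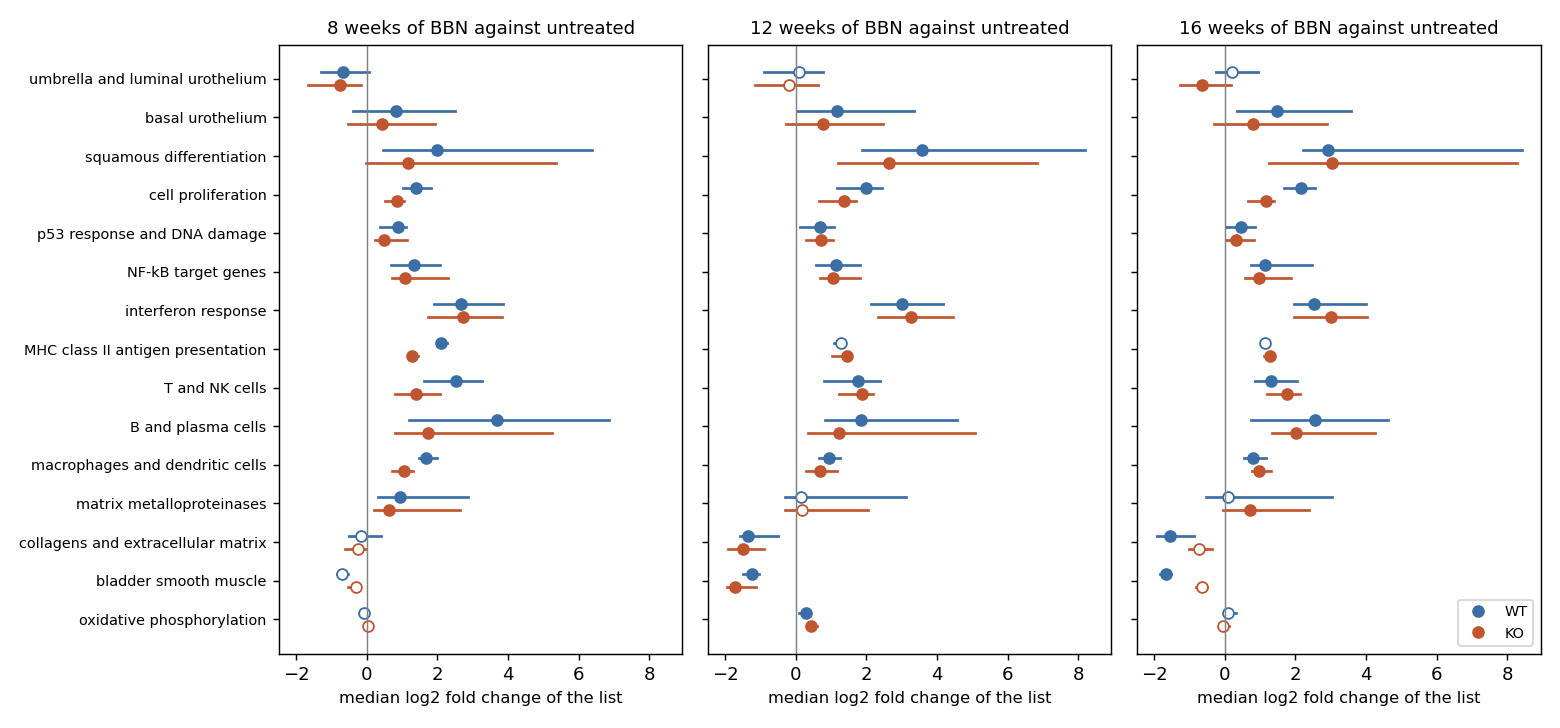
Median log2 change with BBN of 15 gene lists at 8, 12 and 16 weeks against untreated bladder, with WT in blue, the knockout in orange, lines for the quartiles of the list, and filled symbols where the camera adjusted p was at most 0.05. Proliferation genes had a median of 2.17 in WT and 1.18 in the knockout at 16 weeks.

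The responses of the genotypes to BBN were close to each other across genes. The log2 changes of 16189 genes in WT and in the knockout had a correlation of 0.858 at 8 weeks, 0.853 at 12 weeks and 0.807 at 16 weeks, across genes, which are not independent replicates. At 16 weeks 1199 genes rose in both, against 258 for independent calls, 794 fell in both, against 197, and 1 had opposite directions. Krt6a, Krt14, Sprr2f, Isg15, Icam1 and Cdkn1a were among those that rose in both genotypes at all 3 times, and Ttr, Dmgdh, Uchl1 and Upk2 fell in both at all 3 times.

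**Figure D3:**
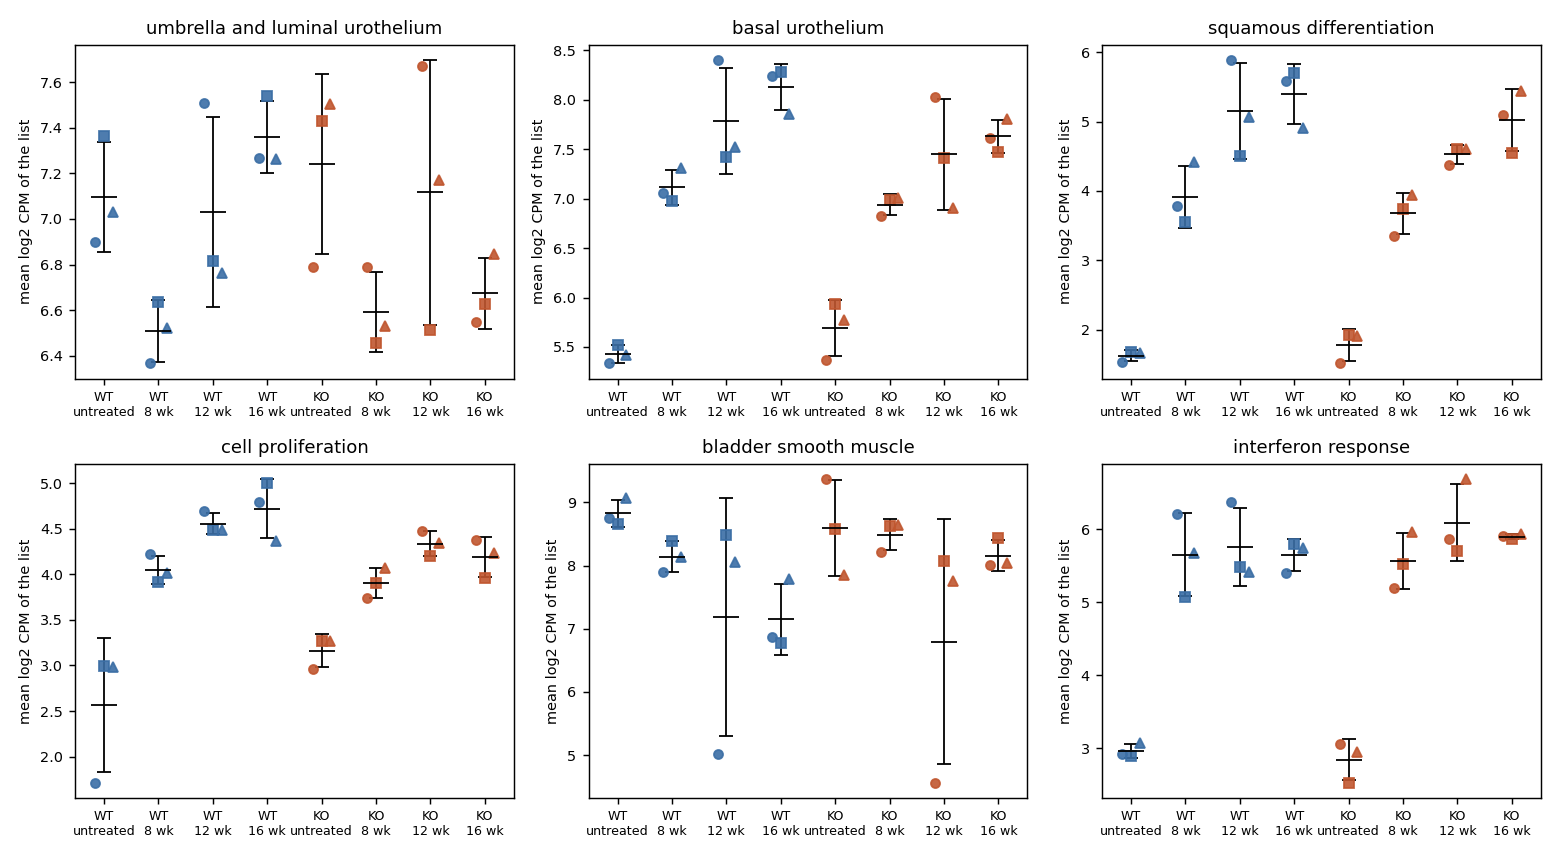
Mean log2 CPM of 6 gene lists in each library by week of BBN, with WT in blue and the knockout in orange. Replicate 1 of both genotypes at 12 weeks lay lowest for smooth muscle genes (5.019 and 4.566).

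The knockout against WT asked what loss of PLD1 changed in the bladder, first averaged over the 4 times. Of 16189 genes 28 differed, 13 higher and 15 lower. The number was 54 with DESeq2, 16 with unique exon reads (3 higher and 13 lower), 46 with introns counted and 50 without the 2 libraries low in smooth muscle. Besides Pld1, Wdfy1 (ENSMUSG00000073643, chromosome 1, 79702262 to 79776143), an adaptor of endosomal Toll-like receptor signalling, was lower by −1.45 ± 0.06 (SE, adjusted p = 3.71e-11), at 23.32 against 63.98 CPM over 12 libraries each. Gm15446 (ENSMUSG00000090015, chromosome 5, 109923400 to 109943936) was higher by 4.27 ± 0.17 (adjusted p = 3.67e-11), at 13.28 against 0.6915 CPM. On chromosome 14, the neighbours Plac9b (2.44 ± 0.28), Tmem254c (2.19 ± 0.17), Tmem254a (2.09 ± 0.20) and Tmem254b (2.07 ± 0.20) were higher, as was 1700112E06Rik (3.38 ± 0.24) elsewhere on it. The call of 1700112E06Rik was lost with introns counted, as was that of Pld1 (adjusted p = 0.093). Gm13301 on chromosome 4 was higher, at 4.091 against 0.1503 CPM over 12 libraries each (adjusted p = 3.03e-05), and the dynein gene Dynlt1b on chromosome 17 lower by −1.30 ± 0.13. The mitochondrial transhydrogenase gene Nnt was lower by −1.15, and Cd59a, Abcc8, Camk2b and Cdk5rap1 were also among the 15 lower genes. Mmp13 stood at −1.29 ± 0.48 (adjusted p = 0.834, and 0.394 to 1 over the alternatives), or −0.83 without replicate 1 of WT at 8 weeks.

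**Figure D4:**
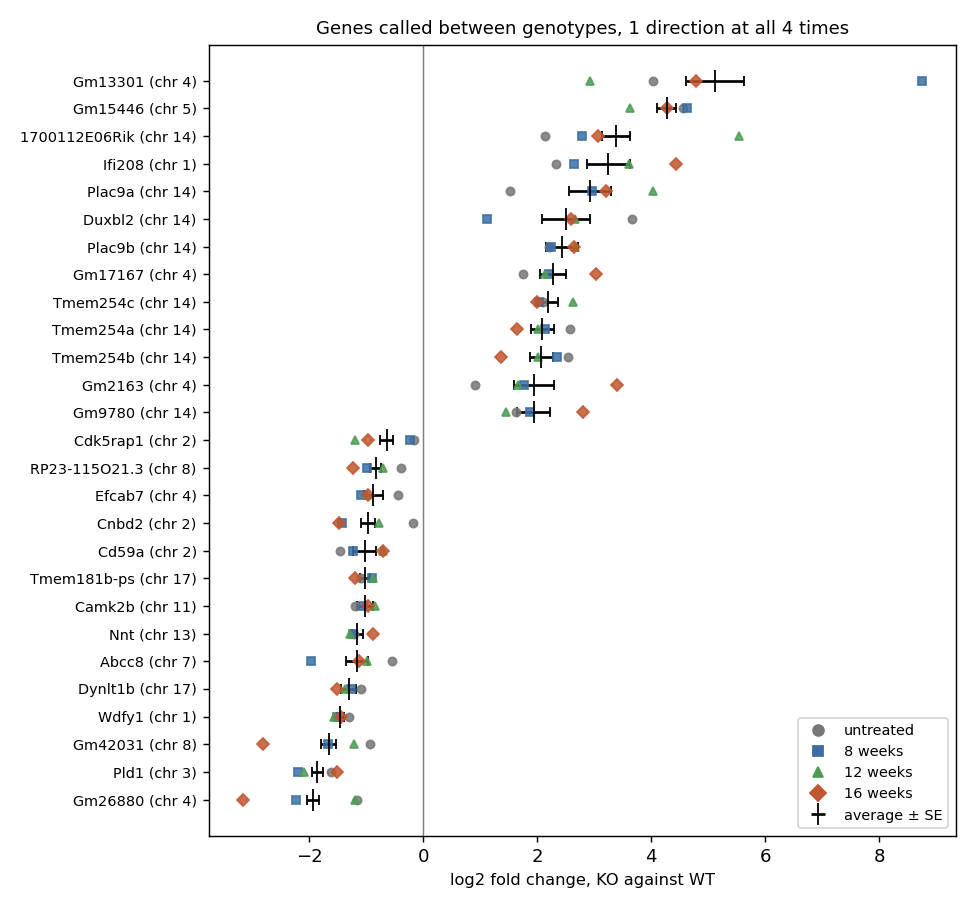
Log2 difference of the knockout from WT at the 4 times for the 27 of 28 genes that differed on average and kept 1 direction at all 4 times, with the chromosome beside each symbol and a black bar for the average ± SE. Gm15446 stood at 3.63 to 4.62 and Wdfy1 at −1.56 to −1.30.

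Averaged over the 4 times, no gene list passed with an estimated correlation, and 13 did with the preset one. B and plasma cell genes had a median of 0.50 (camera adjusted p = 3.7e-07, and adjusted p = 0.79 with an estimated correlation) and MHC class II genes 0.51 (camera adjusted p = 0.000128, and adjusted p = 0.79 with an estimated correlation), and both calls stayed with each of the 24 libraries left out. Squamous genes had a median of −0.20 (camera adjusted p = 0.00029, and adjusted p = 0.79 with an estimated correlation), and the call was lost without replicate 1 of WT at 12 weeks (0.0606). In the xenobiotic metabolism list Cyp1b1 (−0.81 ± 0.18) and Cyp1a1 (−0.78 ± 0.22) were lower over the list alone.

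In untreated bladders 9 genes differed between the genotypes, 5 higher and 4 lower, with 20 in DESeq2. The number was 3 without replicate 1 or 3 of untreated WT or replicate 2 of the untreated knockout, 4 without replicate 3 of the untreated knockout and 20 without its replicate 1. Gm15446 was higher by 4.56 ± 0.34 (SE, adjusted p = 1.6e-06, 15.33 ± 3.309 against 0.6381 ± 0.3487 CPM, SD, n = 3) and Wdfy1 lower by −1.30 ± 0.12 (adjusted p = 2.51e-05). Tmem254a (2.57 ± 0.41), Tmem254b (2.55 ± 0.40), Tmem254c (2.10 ± 0.33), 1700112E06Rik (2.14 ± 0.37), Nnt (−1.21 ± 0.20) and Tmem181b-ps (−1.09 ± 0.18) passed too but lost their calls in 5 to 10 alternatives each, mainly those with a library left out. Wdfy1 lost its call with introns counted. Proliferation genes stood higher in the untreated knockout, with a median of 0.44 and Birc5 at 1.24 ± 0.35 (camera adjusted p = 1.59e-16, and adjusted p = 0.715 with an estimated correlation), and 2 genes passed over the list alone. That call was lost without replicate 1 of untreated WT (0.108), whose mean log2 CPM over these genes was 1.715 against 2.999 and 2.984 in the other 2 libraries.

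At 8 weeks of BBN 12 genes differed, 6 higher and 6 lower, with 26 in DESeq2, 22 with only the compared libraries fitted and 20 without the 2 libraries low in smooth muscle. The number was 5, 6 and 4 without replicate 1, 2 or 3 of WT at 8 weeks, and 4 and 5 without replicate 1 or 3 of the knockout at 8 weeks. Gm13301 was at least 55-fold higher, Gm15446 stood at 4.62 ± 0.35 and Wdfy1 at −1.51 ± 0.12. Gm26880 was lower by −2.23 ± 0.22 (adjusted p = 2.28e-05). Errfi1, a feedback inhibitor of EGF receptor signalling, was higher at 108.1 ± 26.48 against 43.56 ± 3.362 CPM (SD, n = 3, 1.30 ± 0.23, adjusted p = 0.0321), and lost its call in 7 alternatives. Immediate-early genes stood higher in the knockout, with a median of 0.73 and 12 of 23 higher over the list alone, including Zfp36 (0.89 ± 0.19) and Jun (0.65), and this list also passed with an estimated correlation (camera adjusted p = 5.68e-27, and adjusted p = 0.0165 with an estimated correlation). Its mean log2 CPM was 6.255, 5.402 and 6.281 in knockout replicates 1 to 3 and 5.362, 5.105 and 5.13 in those of WT. Knockout replicate 2 thus stood close to WT replicate 1. The list was fixed as immediate-early and dissociation stress genes, and an effect of sample handling was not tested. Mast cell genes stood lower with a median of −1.27 and Cpa3 at −1.50 ± 0.57 (camera adjusted p = 7.96e-05, and adjusted p = 0.372 with an estimated correlation). The median was smaller in size without replicate 1 of WT at 8 weeks, where the list still passed (camera adjusted p = 0.0399). Without the 2 libraries low in smooth muscle, a fit chosen after seeing the data, the immediate-early and mast cell lists both passed with an estimated correlation (adjusted p = 0.0434 each). Skeletal muscle genes stood higher with a median of 2.25 (camera adjusted p = 7.13e-07, and adjusted p = 0.372 with an estimated correlation), a call lost without replicate 3 of the knockout, the library high in these genes (0.455). Mmp13 stood at −1.38 ± 0.67 and turned to 0.37 without replicate 1 of WT, and it passed in none of the alternatives (adjusted p from 0.765 to 1).

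At 12 weeks of BBN 8 genes differed, 4 higher and 4 lower, with 55 in DESeq2, 17 without replicate 3 of the knockout and 0 in edgeR with only the compared libraries fitted. In the fit of all libraries 1201 genes had an unadjusted p below 0.05. Ifi27 was higher at 81.3 ± 10.89 against 42.54 ± 4.509 CPM (SD, n = 3, 0.93 ± 0.13, adjusted p = 0.00203), a gene that did not pass in the average. Gm15446 stood at 3.63 ± 0.32, Wdfy1 at −1.56 ± 0.12, Nnt at −1.28 ± 0.20 and Gm26880 at −1.19 ± 0.21. 1700112E06Rik had 59 reads against 1 (interval of the ratio 11.4 to 2640). Adipose genes stood higher in the knockout with a median of 1.94 (camera adjusted p = 1.17e-06, and adjusted p = 0.784 with an estimated correlation), and not without the 2 libraries low in smooth muscle (0.407). B and plasma cell genes had a median of 0.69 and Jchain stood at 2.37 ± 0.70 (camera adjusted p = 3.75e-05, and adjusted p = 0.784 with an estimated correlation), a call lost without replicate 1 of WT at 12 weeks (0.0653). Mmp13 stood at −1.02 ± 0.69 and did not pass in any alternative (adjusted p from 0.481 to 0.998).

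At 16 weeks of BBN 14 genes differed, 5 higher and 9 lower. Gm26880 was lower at 7.541 ± 1.163 against 66.76 ± 10.62 CPM (SD, n = 3, log2 −3.15 ± 0.22, SE, adjusted p = 3.86e-07) and Gm42031 at 30.1 ± 5.703 against 210.6 ± 56.91 CPM (−2.80 ± 0.26, adjusted p = 1.16e-05). The interferon-inducible gene Ifi208 was higher (4.43 ± 0.79, adjusted p = 0.0316), as were Gm17167 (3.04 ± 0.48), Gm15446 (4.28 ± 0.35) and Tmem254c (1.99 ± 0.33). Dynlt1b (−1.50 ± 0.25), Cnbd2 (−1.47 ± 0.24), Wdfy1 (−1.44 ± 0.12) and RP23-115O21.3 (−1.22 ± 0.20) were lower. Ifi208, Cnbd2, Dynlt1b, RP23-115O21.3, Gm17167 and Tmem254c each lost their calls in 4 to 6 alternatives, mainly those with a library left out.

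The number of genes that differed at 16 weeks depended on the libraries that set the spread. It was 54 with DESeq2, 22 with introns counted, 1055 (380 higher and 675 lower) with only the 6 libraries of week 16 fitted, and 840 (456 higher and 384 lower) without the 2 libraries low in smooth muscle, a fit chosen after seeing the data. Without replicate 1, 2 or 3 of WT at 16 weeks it was 6, 8 and 8, and without replicate 1, 2 or 3 of the knockout 9, 8 and 7. The common biological coefficient of variation was 0.247 with all libraries, 0.173 without those 2 and 0.148 for the 6 libraries. In the fit without those 2, Krt5, Cd44 and Dsg3 were among the lower basal genes, Upk3b, Gata3, Tmprss2 and Krt20 were among 6 lower luminal genes, and Postn, Dcn, Bgn and Thbs2 were higher among matrix genes. The macrophage genes Mrc1, Csf1r and Adgre1 were higher there, the mast cell genes Cpa3 and Cma1 lower, and 0 of 28 proliferation genes passed. These genes were chosen after their values were seen. The authors' deposited table for week 16 listed 1809 genes at an adjusted p of at most 0.05 (1062 higher and 747 lower), of which 1789 were tested here and 12 were also called. All 1789 had the sign found here, which rests on the same 6 libraries. Mmp13 stood at −2.12 ± 0.67 (adjusted p = 0.422, and 0.0565 to 0.801 over the alternatives), with 110 reads in WT against 35 in the knockout, a ratio of 3.61 (95% interval 2.45 to 5.45), and the authors' deposited table gave it a fold change of −4.06 with a corrected p of 0.0021. Without replicate 2 of WT the log2 value was −1.4.

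At 16 weeks 13 lists passed with the preset correlation, 6 higher and 7 lower, and 0 with an estimated one. Proliferation genes stood lower in the knockout with a median of −0.53 (camera adjusted p = 2.1e-08, and adjusted p = 0.678 with an estimated correlation), luminal genes with −0.70 and Krt20 at −3.08 ± 0.81 (camera adjusted p = 2.51e-06, and adjusted p = 0.678 with an estimated correlation), and basal genes with −0.49 (camera adjusted p = 0.00151, and adjusted p = 0.678 with an estimated correlation). Squamous genes had a median of −0.45 and Sprr2f stood at −2.37 ± 0.49 (camera adjusted p = 0.0152, and adjusted p = 0.678 with an estimated correlation), a call lost without replicate 1 or 2 of WT or replicate 2 of the knockout (up to 0.238). Smooth muscle genes stood higher with 0.98 (camera adjusted p = 0.000684, and adjusted p = 0.678 with an estimated correlation), T and NK cell genes with 0.83 (0.00182) and B and plasma cell genes with 0.72 (0.00101). With an estimated correlation these last 2 lists had adjusted p = 0.678 each, and 0.475 and 0.411 without the 2 libraries low in smooth muscle. Without replicate 1 of the knockout at 16 weeks both medians were smaller, and both lists still passed with the preset correlation (camera adjusted p = 0.0344 and 0.0287). Mast cell genes stood lower with −1.10 (camera adjusted p = 0.0152, and adjusted p = 0.678 with an estimated correlation), a call lost without replicate 2 of the knockout (0.0658). Xenobiotic metabolism genes stood lower with −0.44 (camera adjusted p = 0.00351, and adjusted p = 0.678 with an estimated correlation), a call lost without replicate 1 of the knockout (0.0704). Oxidative phosphorylation genes stood lower with −0.13 (camera adjusted p = 0.0065, and adjusted p = 0.697 with an estimated correlation). The other 3 lists were higher. Macrophage and dendritic cell genes stood at 0.62 (camera adjusted p = 0.00397, and adjusted p = 0.678 with an estimated correlation) and MHC class II genes at 0.78 (camera adjusted p = 0.00501, and adjusted p = 0.678 with an estimated correlation). Collagen genes stood at 0.67 (camera adjusted p = 0.0065, and adjusted p = 0.768 with an estimated correlation). These 3 calls were lost without replicate 1 of the knockout, and that of collagens also without replicate 2 of WT (up to 0.0926, 0.0531 and 0.108). Apart from Pld1 in the phospholipase D list, no member of a list passed over all genes, and over the list alone 1 luminal gene (Krt20), 1 squamous gene (Sprr2f) and 1 fibroblast gene (Il33, −1.41 ± 0.33) were lower.

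The last comparison asked whether the response to 16 weeks of BBN differed between the genotypes. No gene passed in edgeR (0 of 16189, smallest adjusted p = 0.0704, 1543 with an unadjusted p below 0.05), and DESeq2 gave 3 (Gm26880, Gm42031 and Gm28539). Gm26880 was also the 1 gene found with introns counted and the 1 found without replicate 2 of untreated WT. Without the 2 libraries low in smooth muscle 1 gene was found, Olfml2b. For a difference at any of the 3 times the number was also 0 (smallest adjusted p = 0.0842, 703 with an unadjusted p below 0.05). It was 6 in DESeq2 and 7 without replicate 1 of the untreated knockout, with Gm26880 among both. It was 1 each with introns counted and without replicate 2 of untreated WT or replicate 1 or 2 of WT at 8 weeks, each time Gm26880. Without the 2 libraries low in smooth muscle it was 1, Olfml2b. In edgeR Gm26880 held the adjusted p of 0.0842. Proliferation genes rose less in the knockout as a list, with a median difference of −0.988 and 12 of 28 lower over the list alone, among them Mcm2 (−0.89 ± 0.21), Mcm7 (−0.83 ± 0.20), Birc5 (−1.72 ± 0.46) and Bub1b (−1.21 ± 0.33) (camera adjusted p = 5.85e-17, and adjusted p = 0.761 with an estimated correlation). Mmp13 stood at −1.49 and did not pass (adjusted p from 0.69 to 0.947 over the alternatives), with −0.76 without replicate 2 of WT at 16 weeks and −0.95 without replicate 3 of the untreated knockout.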

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

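The tests of neighbouring genes, of DNA beside Pld1, of unique reads by direction, of tissue levels for the differing response, of the untreated WT library low in proliferation genes and of clock genes (except Usp2, Wee1 and Nfil3) were chosen only after the results were seen, the other tests before.

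Proliferation genes came up as a difference between the genotypes in the response to 16 weeks of BBN, with a median of −0.988. They also stood lower in the knockout than in WT at that time, with a median of −0.53. Fewer urothelial cells in the knockout samples could give this. With the mean urothelial level as a covariate the median at 16 weeks shrank to −0.26 (camera adjusted p = 0.0198). Part of that difference thus went with the urothelial level, and the remainder cannot be told apart from an imperfect correction. The differing response kept a median of −0.65 with it (camera adjusted p = 1.9e-08), so the level as corrected did not take up all of it. The same covariate turned smooth muscle genes from 0.98 to −0.81 at 16 weeks and from 0.99 to −1.13 for the response, which limits both readings. Smooth muscle level as a covariate left −0.43 at 16 weeks (camera adjusted p = 1.91e-06) and −0.87 for the response. Its slope comes from differences within groups. Their SD (n = 3) was 1.887 in WT and 1.938 in the knockout at 12 weeks, and 0.76 or less in the other groups. The correction at 16 weeks thus rests mostly on libraries of 12 weeks and cannot decide on smooth muscle share. The difference at 16 weeks stayed without the shallow replicate 2 of WT at 16 weeks (adjusted p = 7.59e-06, median −0.39), and the differing response without replicate 1 of untreated WT (1.39e-12, median −0.7). Untreated, the list stood higher in the knockout by 0.44, which adds to the differing response, and that shrank to 0.16 and lost its call without this replicate (0.108). The fits with a library left out argue against those 2 libraries as the whole source. A lower rate of cell division without PLD1 stays open beside a smaller epithelium or a larger share of smooth muscle. The list did not pass with an estimated correlation (adjusted p = 0.761).

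The other lists flagged for a response that differed between the genotypes were as follows. Umbrella and luminal genes had a median difference of −0.996 (camera adjusted p = 0.000125, and adjusted p = 0.943 with an estimated correlation). Basal genes had −0.702 (camera adjusted p = 0.000945, and adjusted p = 0.943 with an estimated correlation). Squamous genes had −0.796 (camera adjusted p = 0.036, and adjusted p = 0.943 with an estimated correlation), a call lost without replicate 1 or 2 of WT or replicate 2 of the knockout at 16 weeks (up to 0.182). Smooth muscle genes had 0.988 (camera adjusted p = 0.000229, and adjusted p = 0.943 with an estimated correlation). Collagen and matrix genes had 0.79 (camera adjusted p = 0.00491, and adjusted p = 0.943 with an estimated correlation). Interferon genes had 0.264 (camera adjusted p = 0.036, and adjusted p = 0.943 with an estimated correlation), a call lost without any 1 of 7 of the 12 libraries (up to 0.299). A fit without the 2 libraries low in smooth muscle (replicate 1 of WT and of the knockout at 12 weeks) was chosen after seeing the data. There the basal, squamous, smooth muscle and interferon lists had camera adjusted p = 0.472, 0.665, 0.642 and 0.856 with an estimated correlation.

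The 28 genes that differed between the genotypes on average lay beside each other more often than genes drawn singly at random. Of them 12 lay within 1 Mb of another, against a highest value of 10 in 10000 random gene sets (permutation p = 1e-04, the smallest these sets can give). Plac9a, Plac9b, Tmem254a, Tmem254b, Tmem254c, Duxbl2 and Gm9780 on chromosome 14 formed the largest group. Of the 28 genes 27 kept 1 direction at all 4 times, which their selection on the average of these times favours. Neighbouring genes that differ together are what strain or copy number variants fixed in 1 of the mouse lines would give. Nnt, which is known to differ between C57BL/6 substrains, was among the 28. Reads shared between near-identical copies could move such genes, and with unique exon reads 16 of the 28 passed again. Of the 15 lower genes 13 did, which argues against shared reads as their source. Of the 13 higher genes 3 did, and the other 10 had too few unique reads to be tested, so shared reads stay open for them. DNA beside the Pld1 locus is argued against, since 0 other genes of the 28 lay within 10 Mb of Pld1 although 66 genes there were tested.

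Clock genes parted the untreated knockout libraries, and other groups. Arntl stood at 25.9 and 22.6 CPM in replicates 2 and 3 against 3.9 in replicate 1, and Dbp at 56.8 and 76.2 against 246.6. A different time of day of collection could give this. All 8 clock output genes other than Per1 and Per2, Dbp among them, were lower by a log2 of at least 0.5 in both replicates. Of all genes 9.76% were. Of 3 genes not looked at before, 2 moved as another time of day would need (Usp2 and Nfil3, but not Wee1), so a different time of day stays open. The file series is argued against by a gap of 0.48 in untreated WT against 3.92 in the knockout, and loss of PLD1 by the clock score of 4.48 in knockout replicate 1, against 4.43 ± 0.42 (SD, n = 3) in untreated WT. Without that replicate the test for a differing response at any time called 7 genes, Arntl, Npas2, Per1, Per2, Leo1, Tsc22d3 and Gm26880. The clock score also differed between whole groups, with means of 3.8, 0.66 and 1.74 in WT and 4.19, 1.23 and 1.52 in the knockout at 8, 12 and 16 weeks, against 1.87 ± 2.28 in the untreated knockout. Clock genes thus shifted in the comparisons of BBN at 12 and 16 weeks in WT and at 8 weeks in the knockout, of the untreated genotypes, and of the response. Whether BBN or the time of collection moved the treated groups was not tested.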

How the results depend on the processing

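The fits without the 2 libraries low in smooth muscle (replicate 1 of WT and of the knockout at 12 weeks) and the list tests with a library left out were tests chosen only after the results were seen. The cause of a change was not tested unless it is given.

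Of 651 called values of named genes 443 kept their call in every setting. With only the compared libraries fitted, which leaves fewer samples to set the spread, the genes changed with BBN numbered 5768 in WT at 8 weeks, 1514 in WT at 12 weeks and 365 in the knockout at 12 weeks, and the genes that differed between the genotypes 22 at 8 weeks, 0 at 12 weeks and 1055 at 16 weeks. DESeq2 gave 20, 26, 55 and 54 genes for the genotypes at the 4 times, 54 on average, 3 for the differing response at 16 weeks and 6 at any time. With introns counted the numbers were 5331 for BBN in the knockout at 8 weeks, 22 for the genotypes at 16 weeks, 46 on average, 1 for the response at 16 weeks and 1 at any time, and 1700112E06Rik turned to −0.15 at 8 weeks. Unique exon reads gave 16 genes on average. Without the 2 libraries low in smooth muscle, BBN changed 5316 genes at 8 weeks and 4414 at 16 weeks in the knockout, the genotypes differed in 20 at 8 weeks, 840 at 16 weeks and 50 on average, and the response in 1 at 16 weeks and 1 at any time. RLE scaling and the fit without a filter kept each number within 1.5 times.

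With single libraries left out, BBN changed 2231 to 2877, 3551 to 5846 and 3222 to 4448 genes in WT and 2055 to 3890, 3504 to 5686 and 1646 to 2879 in the knockout at 8, 12 and 16 weeks. The genotypes differed in 3 to 20, 4 to 8, 7 to 17 and 6 to 9 genes at the 4 times and 25 to 36 on average, and the response in 0 to 1 at 16 weeks and 0 to 7 at any time. Fewer samples also lower these numbers.

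Gene lists depended most on the correlation between genes. With an estimated correlation 0 lists passed in each of the 6 BBN comparisons (0 against 13 to 19), 0 between the genotypes untreated, at 12 weeks, at 16 weeks and on average, 0 for the response at 16 weeks, and 1 at 8 weeks. The fit without the 2 libraries low in smooth muscle was chosen after seeing the data. In it the luminal, collagen and smooth muscle lists that fell with BBN did not pass with an estimated correlation either (camera adjusted p from 0.358 to 0.694). List medians moved by over 1.5 times without single libraries. Among those of the genotypes, mast cell genes at 8 weeks went from −1.27 to −0.54 without replicate 1 of WT, and skeletal muscle genes from 2.25 to 0.13 without replicate 3 of the knockout. At 16 weeks B and plasma cell genes went from 0.72 to 0.27 and T and NK cell genes from 0.83 to 0.51 without replicate 1 of the knockout. For the response, smooth muscle genes went from 0.988 to 1.96 and 0.63 without replicates 1 and 3 of the untreated knockout. With BBN at 12 weeks in the knockout, smooth muscle genes went from −1.72 to −0.86 without replicate 1 of the untreated knockout, and T and NK cell genes from 1.89 to 0.74 without replicate 3. In untreated bladders the 3 lists became 5 without the file series term and 9 without the 2 libraries low in smooth muscle. With single libraries left out, 5 to 7 lists differed between the genotypes untreated, 5 to 13 at 8 weeks, 7 to 15 at 12 weeks, 9 to 17 at 16 weeks and 6 to 17 on average.

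For the gene list endothelium, KO vs WT at 12 weeks, the direction turned to lower in the knockout without replicate 1 of WT at 12 weeks (adjusted p = 0.000179), and over the libraries left out its adjusted p ranged from 1.67e-05 to 0.397.

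With the replicate number as a block in place of the file series, 3402, 5106 and 5116 genes changed in WT and 3408, 5189 and 2701 in the knockout, the genotypes differed in 8, 10, 7 and 14 genes and 28 on average, and 6 lists differed untreated. Libraries with the same number had a median correlation of residuals of 0.0355, 0.00629 and 0.000976 over 28 pairs each, so the medians gave no hint of pairing. Single pairs ranged from −0.487 to 0.588, −0.285 to 0.532 and −0.315 to 0.313, with 9, 6 and 8 pairs above 0.1.

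Depth limits genes of few reads, such as Mmp13 with 4 and 2 reads in the untreated groups, where 1 read more or less moves the ratio within its interval.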

Other observations

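The tests of the authors' deposited table by the exact test, the splits of that test, and the fit and splits without the 2 libraries low in smooth muscle were chosen only after the results were seen.

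Several lists gave smaller or mixed changes with BBN. At 16 weeks in WT, the epithelial-mesenchymal transition list had 3 genes higher and 1 lower of 15, a median of −0.75 and no call (camera adjusted p = 0.649), with Tgfb1 higher by 1.09 ± 0.14 (SE) and Fn1 lower by −1.86 ± 0.60. Endothelium genes had a median of −0.05 (camera adjusted p = 0.72), and Pecam1 stood at 0.03 ± 0.47. Metalloproteinase inhibitors had 1 higher and 2 lower of 5, a median of −0.91 (camera adjusted p = 0.309) and Timp2 at −0.92 ± 0.29. Activated fibroblast genes had 5 of 16 higher, with a median of −0.23 while the mean (0.77) and the test were on the other side (camera adjusted p = 0.321), and Pdpn stood at 0.85 ± 0.27. Xenobiotic metabolism genes went both ways (7 higher and 3 lower of 24, camera adjusted p = 0.321), with Aldh1a3 at 2.41 ± 0.41 and Cyp1a1 at −2.42 ± 0.43. Glycolysis and hypoxia genes had 8 higher and 5 lower of 24 (camera adjusted p = 0.155), with Car12 at 3.64 ± 0.54 and Pdk1 at −0.77 ± 0.11, and oxidative phosphorylation genes 6 higher of 25 (camera adjusted p = 0.253).

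Skeletal muscle genes had 4 of 12 lower at 16 weeks in WT (camera adjusted p = 0.0825), with Acta1 at −3.95 ± 0.81, and nerve and glia genes 1 higher and 2 lower of 12 (camera adjusted p = 0.873). Erythrocyte genes had 1 of 7 higher (camera adjusted p = 0.321), adipose genes 0 of 11 (camera adjusted p = 0.419), mast cell genes 2 higher and 1 lower of 9 (camera adjusted p = 0.155), and immediate-early genes 8 of 23 higher with Hspa1b at 1.73 ± 0.19 (camera adjusted p = 0.000706, and adjusted p = 0.48 with an estimated correlation). In the phospholipase D family, Pld3 rose in WT by 0.78 ± 0.10, 0.59 ± 0.10 and 0.40 ± 0.10 at 8, 12 and 16 weeks and in the knockout by 0.69 ± 0.10, 0.45 ± 0.10 and 0.54 ± 0.10, while Pld2 stood at 0.17 ± 0.08 at 16 weeks in WT. Among male accessory gland genes Spink5, which is also an epidermal gene, rose at 16 weeks in WT from 1 read in the untreated group, a ratio of 347 (95% interval 61.7 to 13700). The sex-linked gene Xist fell at 12 weeks in the knockout (−1.13 ± 0.33, adjusted p = 0.0144).

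For week 16, the quasi-likelihood test called 1055 genes on the 6 libraries alone and 15 without the filter on low counts, against 1809 in the authors' deposited table. An exact test with tagwise dispersions on the 6 libraries called 1845, 1793 of them shared with the authors' deposited table, and over 6 settings of scaling and prior it called from 1792 to 2768. It used the deposited expression values of all 49585 genes, without a filter on low counts. The quasi-likelihood test used the deposited exon reads. Of the 10 splits of these libraries, 1, the real one, gave as many calls, and the highest other gave 32. With 10 splits, their number is too few for a share under 0.05. The authors' deposited table gave Pld1 a fold change of −2.93 with a corrected p of 1.33e-11.

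Splits of 3 against 3 libraries number 10, too few for a share under 0.05. With BBN in WT the real split gave 3489, 5226 and 5284 genes at 8, 12 and 16 weeks and the highest other 0, 13 and 0, and in the knockout 3503, 5302 and 2779 against 0, 702 and 0, each with 1 split as large, the real one. For the knockout against WT the real split gave 9 genes untreated, 12 at 8 weeks and 14 at 16 weeks, each against a highest other of 0 and with 1 split as large, and 840 without the 2 libraries low in smooth muscle, again with 1 and a highest other of 0. At 12 weeks 5 of the 10 splits gave 8 or more, and the highest gave 2882, with the 2 libraries low in smooth muscle and replicate 3 of the knockout against the other 3, which points to a structure of the samples. For the average over 4 times 3 of 100 drawn splits, the real one included, gave 28 or more. This share is under 0.05, so it argues against chance as the whole source but does not exclude it. The highest other gave 2493 and parted the 12 week libraries in that same way. The only other draw with 28 or more calls (571) parted them so too, but the remaining draws that parted them so gave 0 to 10, so that parting alone did not suffice. How those draws parted the 12 week libraries was looked at after their counts were seen. For a differing response at 16 weeks and at any time the real count was 0, so all 100 of 100 splits had to give as many (highest others 0 and 2340) and the splits tested nothing there. The draw with 2340 also parted the 12 week libraries in that way, which points to the same structure.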
